A study of Mus musculus and Rattus norvegicus with 6 samples.

How the data were processed

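Total RNA of liver was extracted with Trizol and hybridised to Affymetrix arrays, per the labels' protocols, 1 array per group: 3 groups of mice and 3 of rats. The deposited values are linear probe set signal intensities that the authors made with MAS5, per the submitters' processing notes, which give no version. MAS5 reduces the probe pairs of a probe set to 1 signal and scales each array to a common trimmed mean. The trimmed mean of the deposited intensities, leaving out 2% at each end, was 496 to 497 on all 6 arrays, while the medians differed. MAS5 signals of dim probe sets are noisy, and without detection calls among the values used here a floor had to stand in for them. The image files, cell-level intensities and animal numbers were not used here. The leptin dose in the labels, 1 microg/mg as written, is not interpreted.

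Gene symbols came from the platform annotation. In mice, 34945 of 45037 probe sets had exactly 1 symbol, 932 had several and 9160 were unnamed; 34741 of the first were updated through their gene identifier to the symbols of assembly GRCm38.p6 and 204 kept the old symbol. In rats, 20826 of 31042 had 1 symbol, 436 several and 9780 none, and symbols stayed as annotated. Probe sets with several symbols or none were left out. Neither coordinates nor a rat assembly were used here.

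The choices that follow were fixed before the data were examined, except where said. Values were used as deposited. The floor was the median of all values of a platform, 82.7 in mice and 97.0 in rats. A gene was represented by its probe set of highest mean signal and entered a comparison if at least 1 of the 2 arrays reached the floor. Lower values were raised to the floor, the log2 ratio was taken, and a gene counted as higher or lower at 2-fold. A ratio with an array under the floor is a bound. Because each group is 1 array, no test was run and leaving out replicates was not possible. The spread between probe sets of the same gene is given as a measure of technical error; it holds nothing of the variation between animals. Comparisons were mutant saline against WT saline and mutant leptin against mutant saline in each species, the overlap of the species by identical symbol, and the share of genotype-changed genes that moved at least 1.5-fold toward WT after leptin, with an exact binomial (Clopper-Pearson) interval.

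Gene lists, 35 in all and 33 in each species, covered pathways of liver metabolism, hormone response, stress and inflammation, and markers of the cell types that a liver sample can hold. A list's median log2 ratio was placed among those of 10000 random lists of the same size, drawn from 10 bins of mean signal. This describes these arrays and is no test. A list stood apart outside the 2.5th to 97.5th percentiles, and a list with fewer than 3 measured members got no median. Named genes were the 10 largest ratios per direction and comparison that were also 2-fold after quantile normalization and had no other probe set 1.5-fold the other way, up to 4 members per list with the largest ratios, any member needed to show the opposite direction, and genes fixed beforehand, among them Lep, Lepr, Igfbp2, Socs3, Scd1, Srebf1, Pck1 and G6pc. G6pc had no measured value in rats.

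Simulated unchanged arrays were made by adding noise drawn from pairs of probe sets of the same gene in the leptin comparison, 100 sets per species. The outcome depended on how that noise was drawn, and 3 noise models were tried. The first paired probe sets within 4-fold in signal, in 10 bins, on log2 signals. It gave 301 genes 2-fold apart in mice and 143 in rats, more than the 49 and 50 measured after leptin. The second (pairs within 2-fold, 20 bins) gave 139 and 39.3, and the third, which drew noise on log2(signal + floor), 27.6 and 3.34. The second and the third were made after these counts had been seen beside the measured ones, so all 3 are reported and none is used as the chance level. The covariance of genotype and leptin ratios, first to be set against the simulated one, gave opposite answers under different models. It was then replaced by a split in which the ratios came from different probe sets of a gene, a test chosen after those answers were seen. As that covariance covers all genes, the genotype-changed genes that moved at least 1.5-fold on another probe set were counted as well, toward and away from WT, a test chosen after the counts were seen.

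The calculations were tested on simulated data with 200 seeded changes in the leptin comparison, under each noise model. Of genes changed 3-fold, 85.0% to 87.5% were recovered as 2-fold in mice and 87.0% to 89.0% in rats, and of genes changed 1.5-fold 2.0% to 5.0% in mice and 2.5% to 4.5% in rats. These steps ran on 11739 to 12339 genes in mice and 9669 to 10071 in rats. Alternatives were quantile normalization, arrays centred on their median, floors at the 25th and 75th percentiles, the median over probe sets of a gene, and leaving out probe sets that can bind several transcripts (_x_at and _s_at). A size of 1.5-fold for leptin, the second and the third noise model and the probe set split with its counts were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.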

Results

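Liver RNA was profiled on short-oligonucleotide arrays in leptin-deficient mice and rats and in their wild-type (WT) littermates. Leptin is the hormone that adipose tissue secretes in proportion to its fat, and animals without it overeat and become obese. Mice homozygous for the Lepob allele had a C57/BL6J background, and rats homozygous for the Lepmkyo allele an F344/NSlc background. The labels of the rats conflict: their titles spell the genotype in different ways and their source field names Lepob, so Lepmkyo was taken from the descriptions and the design text. Animals were labelled male and 20 weeks old, and liver was taken 6 h after an intraperitoneal injection. Each species contributed 3 arrays: WT given saline, mutant given saline and mutant given leptin. Every group held 1 array, and whether an array carried RNA of 1 animal or of a pool was not stated. No replicate spread could therefore be measured, no test across groups was possible and no p-value is given. "Higher" and "lower" compare the signals of 2 arrays, and a fold against an array under the signal floor is given as "at least". The floor was a signal of 82.7 in mice and 97.0 in rats. The mouse arrays held 45037 probe sets with median signals of 77.0 to 91.9, and the rat arrays 31042 with medians of 93.6 to 99.3. The number of arrays limits the precision of each value.

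The leptin transcript, Lep, was far under the floor on all 6 arrays, with signals of 2.8 to 6.0, so the arrays gave no check of the Lep genotype in liver. Over probe sets above the floor on all 3 arrays of a species, the log2 signals of the saline and leptin mutant arrays correlated at r = 0.991 in mice and 0.988 in rats. The WT saline and mutant saline arrays correlated at 0.949 in mice and 0.962 in rats. These correlations run across probe sets, which are not independent replicates.

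The comparison of saline-injected mutant and WT mice sets 1 array of leptin-deficient liver without leptin treatment against 1 WT array. The lists of lipid storage and of fatty acid oxidation had higher medians in the Lepob/Lepob liver and that of cholesterol synthesis a lower one. Among sex-biased genes of the liver, the female-biased list had a higher and the male-biased list a lower median. Of 11956 genes measured, 533 were at least 2-fold higher and 443 at least 2-fold lower in the mutant. Cidea, a lipid droplet protein that promotes droplet growth, was at least 178-fold higher, with a signal of 14758 against 18.8. Its relative Cidec was at least 38.0-fold higher. Hsd3b5, a male-specific steroid dehydrogenase of mouse liver, was at least 201-fold lower, and the organic anion transporter Slco1a1 was 122-fold lower.

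Among the lipid droplet and PPARG targets, 13 of 20 measured genes were at least 2-fold higher and 0 were 2-fold lower. The median log2 ratio was 1.38, above all 10000 random lists of matched signal. Besides Cidea and Cidec, the monoacylglycerol acyltransferase Mogat1 was at least 15.6-fold higher and the fatty acid translocase Cd36 was 15.2-fold higher. Of 28 genes of fatty acid oxidation and PPARA targets, 13 were at least 2-fold higher and 0 lower, with a median of 0.90, also above all random lists. Cyp4a14, a fatty acid omega-hydroxylase, was 38.7-fold higher, the acyl-CoA thioesterases Acot3 and Acot2 were 29.1-fold and 6.77-fold higher, and the pantetheinase Vnn1 was 7.36-fold higher. The adipocyte markers, of which 4 were measured, had a median of 1.76 at the 99.99th percentile. Of these, 3 were at least 2-fold higher and all 3 are also in the lipid droplet list: Cidec, Pparg (3.95-fold) and the adipocyte fatty acid binding protein Fabp4 (2.89-fold).

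Cholesterol synthesis and uptake genes lay at a median of -1.04, below all random lists, with 12 of 20 at least 2-fold lower and 0 higher. Farnesyl diphosphate synthase (Fdps) was 4.59-fold lower, isopentenyl diphosphate isomerase (Idi1) 3.78-fold, lanosterol demethylase (Cyp51) 3.47-fold and 7-dehydrocholesterol reductase (Dhcr7) 3.31-fold lower. The lipogenesis and triglyceride synthesis list did not stand apart: its median of 0.13 lay at the 79.0th percentile, with 1 of 23 genes 2-fold higher and 1 lower. Thrsp, a lipogenic regulator, was 2.34-fold higher and Mlxipl, the carbohydrate response element binding protein, 2.41-fold lower. Scd1, the stearoyl-CoA desaturase, was 1.26-fold lower on its brightest probe set while another had a log2 ratio of 0.35, and Srebf1, the lipogenic transcription factor, was 1.19-fold higher. Glycolysis, fructose and pentose phosphate genes had a median of 0.52 at the 99.96th percentile, with 1 of 17 genes 2-fold higher, hexokinase 2 (Hk2) at 2.97-fold, and 0 lower. The gluconeogenesis and fasting list had a median of 0.60 at the 99.99th percentile, and 5 of 19 genes were at least 2-fold higher and 0 lower, led by the alanine transaminase Gpt2 at 3.81-fold. The gluconeogenic enzyme Pck1 was 1.07-fold lower on its brightest probe set, while another of its probe sets had a log2 ratio of -2.01. G6pc, the glucose-6-phosphatase, was 1.40-fold lower.

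Female-biased liver genes had a median log2 ratio of 2.46, above all random lists, with 8 of 12 at least 2-fold higher and 0 lower. The cytochromes P450 Cyp2b9 and Cyp2b13 were 86.0-fold and at least 32.5-fold higher. Cyp4a14 and Acot3 are in this list as well as among the PPARA targets. Male-biased genes had a median of -1.68, below all random lists, with 7 of 13 at least 2-fold lower and 0 higher. Besides Hsd3b5 and Slco1a1, the oxysterol hydroxylase Cyp7b1 was 43.0-fold lower and the fatty acid elongase Elovl3 11.5-fold lower. Genes of leptin, insulin and growth hormone signalling had a median of -0.28 at the 0.27th percentile, with 3 of 25 at least 2-fold higher and 4 lower. Igfbp2, an insulin-like growth factor binding protein, was 12.7-fold lower, and Socs2, a growth hormone target, 7.23-fold lower on its brightest probe set and at a log2 ratio of -0.27 on another, whereas the fasting hormone Fgf21 was 5.81-fold higher. The leptin receptor, Lepr, was at least 3.11-fold higher on its brightest probe set, but another of its probe sets had a log2 ratio of -0.41. Socs3, a feedback inhibitor of cytokine signalling, was 1.89-fold higher on its brightest probe set and at 0.29 on another.

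Clock genes stood apart in the mouse liver, with 9 of 16 at least 2-fold higher, 3 at least 2-fold lower and a median of 1.06, above all random lists. The output factor Dbp was 24.7-fold higher, Per3 at least 8.78-fold, Per2 6.43-fold and Ciart at least 6.08-fold higher. Arntl, the activator of the opposite phase, had a log2 ratio of -2.14. The hour of collection was not stated for either group, and whether it bears on other lists was not tested. Metallothioneins Mt1 and Mt2 were 16.0-fold and 8.75-fold higher in a list of NRF2 and oxidative stress genes with a median of 0.45 at the 99.94th percentile, where 3 of 16 were at least 2-fold higher and 0 lower. The xenobiotic metabolism list had a median of 0.40 at the 99.98th percentile, although 5 of its 29 genes were at least 2-fold higher and 5 at least 2-fold lower. Abcb1a, a drug efflux pump, was at least 8.97-fold higher, and Cyp1a2 was 3.72-fold lower.

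Acute phase proteins had a median of -0.26 at the 0.155th percentile, with 2 of 25 at least 2-fold higher and 2 lower. The serum amyloids Saa2 and Saa1 were 6.89-fold and 2.92-fold lower, but Orm3 5.93-fold and the siderophore-binding protein Lcn2 4.47-fold higher. Endoplasmic reticulum and amino acid stress genes had a median of -0.37 at the 0.08th percentile, again with 2 of 25 at least 2-fold higher and 2 lower. Sdf2l1 was 5.02-fold and the disulfide isomerase Pdia6 2.76-fold lower, and Trib3 2.27-fold higher. Marker lists of some other liver cells had higher medians. Kupffer cell and macrophage markers had a median of 0.67, above all random lists, with 6 of 22 at least 2-fold higher and 1 lower. Gpnmb was at least 6.70-fold higher and the adaptor Tyrobp 3.18-fold higher. Stellate cell and matrix markers had a median of 0.48 at the 99.98th percentile, with 2 of 18 at least 2-fold higher and 0 lower, and 17 hepatocyte markers a median of -0.33 at the 0.17th percentile, 0 of them 2-fold apart. Lists of few markers stood apart as well: bile duct at -0.90 (1 of 5 higher, 2 lower), red blood cell at -0.55 (0 of 4 higher, 2 lower) and lymphocyte at 0.42 (0 of 5 at 2-fold). The last 2 turned sign in other settings. Amino acid and urea metabolism lay at -0.18 at the 0.905th percentile, with 2 of 29 lower, among them the homocysteine enzyme Cbs at 2.80-fold.

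Other genes among the 10 largest ratios in each direction were higher for the estrogen sulfotransferase Sult1e1 (at least 38.5-fold), Ly6d (37.7-fold) and the lysophospholipid transporter Mfsd2a (log2 ratio 4.64). Lower were Serpina4-ps1 (43.6-fold), Moxd1 (at least 38.4-fold), the major urinary protein Mup10 (20.5-fold), the epidermal growth factor receptor Egfr (19.8-fold, with another of its probe sets at a log2 ratio of 0.03), the glucuronosyltransferase Ugt2b38 (19.0-fold) and the vasopressin receptor Avpr1a (12.4-fold). Of the 33 lists with a median, 21 stood apart, against 1.65 for lists of genes drawn at random. Members of a list can vary together, so 1.65 is no chance level for these lists. The gluconeogenesis, acute phase, NRF2, amino acid, hepatocyte, bile duct, lymphocyte and red blood cell lists did not stand apart in at least 1 other setting. The spread between probe sets of the same gene was 0.42 (SD of log2 ratios, pooled over 4484 genes). Floors at the 25th and 75th percentile gave 984 and 267 genes higher and 1341 and 198 lower.

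**Figure D1:**
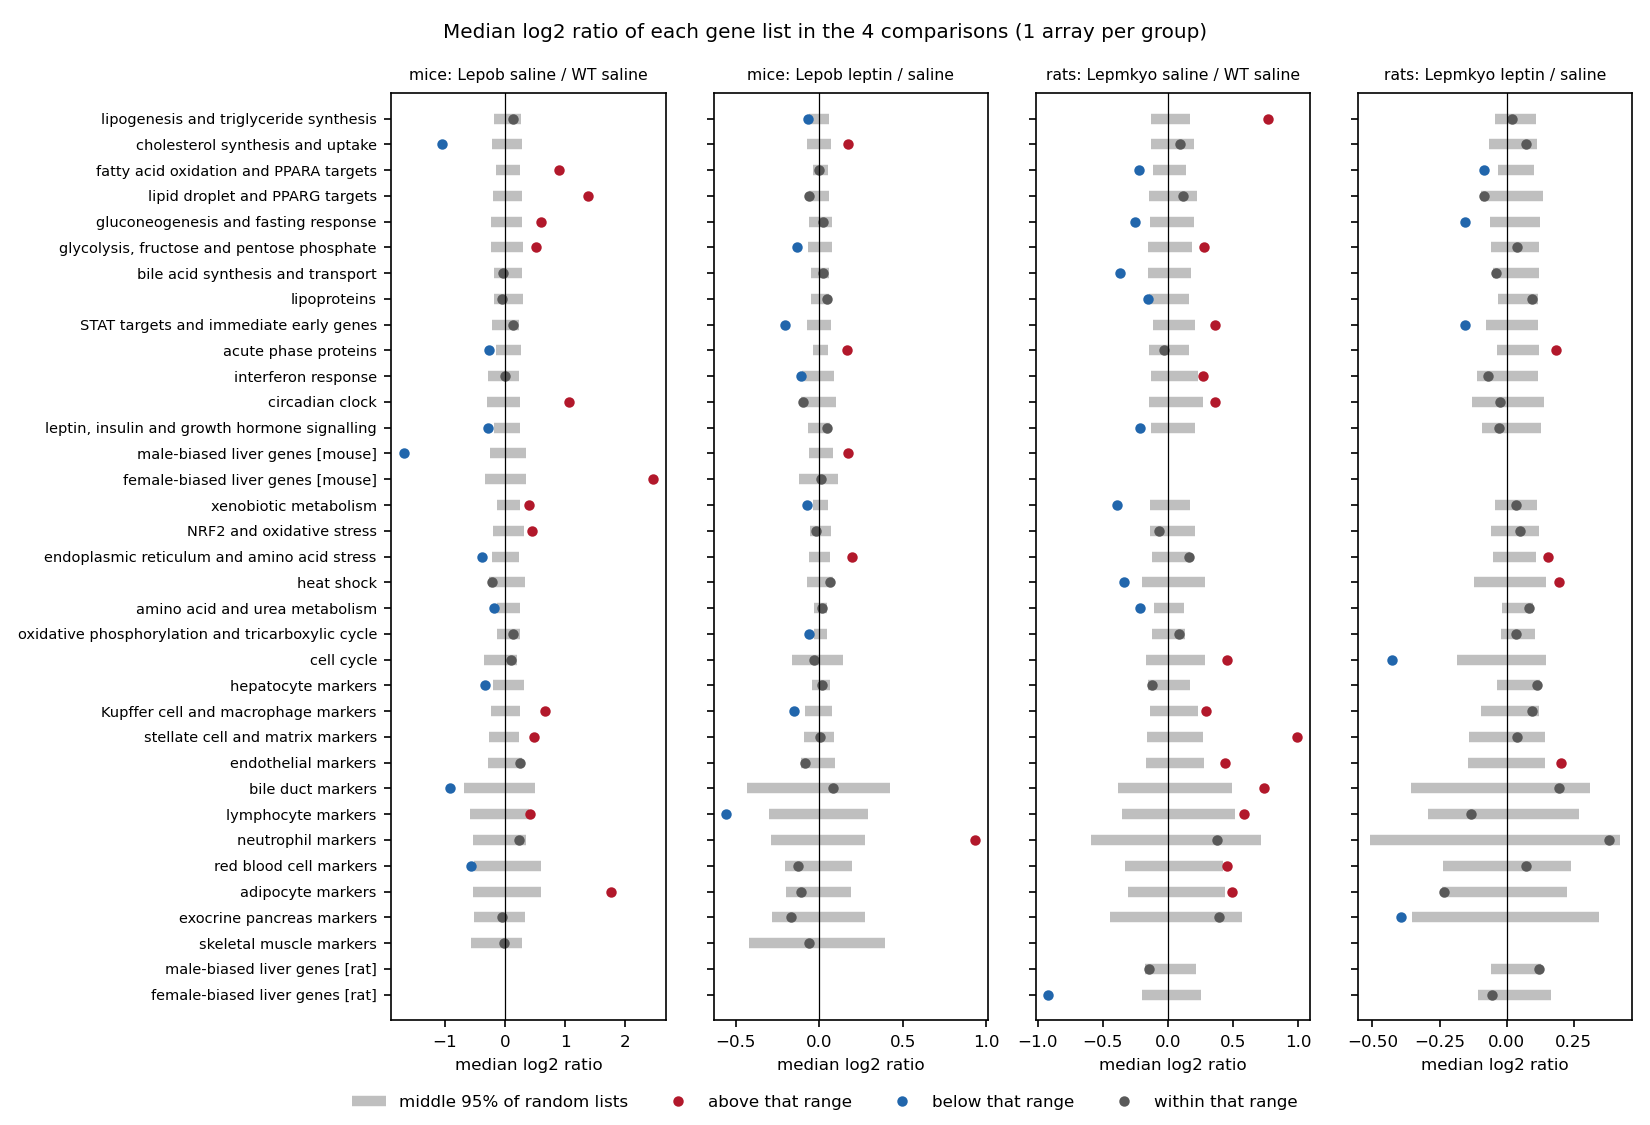
Median log2 ratio of each gene list (horizontal axis) in the 4 comparisons, 1 panel each with its own scale; bars span the middle 95% of 10000 random lists of matched signal, and colour shows medians above, below or within that span. Female-biased genes at 2.46 had the highest and male-biased genes at -1.68 the lowest median in the mouse genotype panel, and neutrophil markers at 0.93 in the mouse leptin panel.

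The stated aim of the leptin injection was to find genes that respond early, before food intake and body weight change. At 6 h the liver of leptin-injected Lepob/Lepob mice differed little from that of saline-injected ones. Of 11536 genes, 21 were at least 2-fold higher and 28 at least 2-fold lower. The list of STAT targets and immediate early genes had a lower median, while the medians of the acute phase, endoplasmic reticulum stress and cholesterol synthesis lists were slightly above 0, with 0 members at 2-fold. The median of neutrophil markers was higher, from 4 of 6 genes. These counts cannot be set against a known chance level: in simulated unchanged arrays, 27.6, 139 or 301 genes in all were 2-fold apart, depending on which of 3 noise models was used, beside the 49 measured.

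Neutrophil markers had a median log2 ratio of 0.93 over 6 genes, above all random lists, with 3 at least 2-fold higher and 0 lower, 4 above 0 and 2 below. Csf3r, the receptor of a neutrophil growth factor, was 1.47-fold lower and the cytokine Il1b 1.19-fold lower. The calprotectin subunits S100a8 and S100a9 were 2.85-fold and 2.61-fold higher and the granule protein Ngp 2.23-fold higher. STAT targets and immediate early genes had a median of -0.21, below all random lists, with 2 of 27 at least 2-fold lower and 0 higher. The phosphatase Dusp1 was 2.31-fold lower, Junb 2.23-fold, Fos 1.91-fold and Btg2 1.76-fold lower, the last with another probe set at a log2 ratio of 0.03. Socs3, a target of leptin-activated STAT3, was 1.35-fold lower on its brightest probe set, and another of its probe sets had a log2 ratio of -0.01. Acute phase proteins had a median of 0.17, above all random lists, with 22 of 25 above 0 and 0 at least 2-fold apart. Saa2 was 1.71-fold, Lcn2 1.51-fold and Saa1 1.43-fold higher. Endoplasmic reticulum and amino acid stress genes had a median of 0.20, with 20 of 25 above 0, and cholesterol synthesis genes a median of 0.17, with 15 of 20 above 0, both above all random lists. Sdf2l1 was 1.88-fold, asparagine synthetase (Asns) 1.59-fold and Fdps 1.36-fold higher.

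Male-biased genes had a median of 0.17 at the 99.98th percentile, with Slco1a1 2.99-fold and Cyp7b1 1.75-fold higher. Another probe set of Slco1a1 had a log2 ratio of 0.23, and the list did not stand apart in at least 1 other setting. The female-biased list did not stand apart, with a median of 0.01 at the 60.7th percentile, although Cyp2b13 was 5.36-fold lower and the sulfotransferase Sult2a2 at least 2.93-fold higher. Lists that stood apart with small negative medians were glycolysis, fructose and pentose phosphate (-0.13), Kupffer cell and macrophage markers (-0.15), interferon response (-0.11), xenobiotic metabolism (-0.07), lipogenesis (-0.07) and oxidative phosphorylation (-0.06). In the first of these Hk2 was 1.41-fold lower, and in the lipogenesis list Thrsp was 1.70-fold lower. Lymphocyte markers had a median of -0.56 over 5 genes, a value that turned to 0.20 with the lower floor. The clock list did not stand apart, with Nr1d1, a repressor of the clock, 2.19-fold lower. That list holds genes of opposite phase: the Per and Dbp phase had a median of -0.01 over 10 genes and the Arntl phase -0.35 over 4. These medians were not placed among random lists.

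Of the largest ratios, several had a signal near or under the floor of 82.7 on 1 of the arrays. Among these, Lce1h was at least 7.16-fold higher, Rfx1 2.79-fold, Plekhm2 at least 2.32-fold and Maz at least 2.28-fold higher. Clcn5, with signals of 827.5 and 298.2, was 2.77-fold higher on its brightest probe set but had a log2 ratio of -0.0466 as the median of its probe sets. Lce1h, Slco1a1, Clcn5, S100a9 and Zbtb16 were under 2-fold in at least 1 other setting, and a probe set of Zbtb16 had a log2 ratio of 0.09. Stk10 was at least 3.72-fold lower, H2bc22 at least 3.39-fold, Foxq1 3.31-fold, Nacc1 at least 2.74-fold, Zbtb16 2.38-fold, Aars2 2.27-fold and Mid1 at least 2.27-fold lower. Phlda1 was 2.52-fold lower at signals of 1901 against 4790. Igfbp2 was 1.40-fold higher, and Lepr, Scd1, Srebf1, Pck1 and G6pc differed by 1.05-fold to 1.13-fold. The probe set spread was 0.24, and 13 of 33 lists stood apart. The saline mutant array is also in the genotype ratios, so its own deviations can give a list opposite medians in the genotype and leptin comparisons. Comparison with random lists does not remove this. Of the lists that stood apart here, all but the neutrophil list had a genotype median of the opposite sign. With the floor at the 75th percentile 5 genes were 2-fold higher and 4 lower, and with it at the 25th percentile 408 and 436.

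The saline mutant and WT rats give the same contrast in the other species. In the Lepmkyo/Lepmkyo rat liver, the lists of lipogenesis and of stellate cell and matrix markers had higher medians. The medians of the fasting response, amino acid, bile acid and xenobiotic lists were lower by small amounts. At least 2-fold lower were 5 of 19 members of the fasting list and a smaller part of the others. Of 9817 genes, 294 were at least 2-fold higher and 142 at least 2-fold lower. Pnpla3, a triglyceride lipase family member of lipogenic liver, was 42.1-fold higher on its brightest probe set, at a signal of 4100 against a WT signal just above the floor, and another of its probe sets had a log2 ratio of 1.81. A1bg, a plasma glycoprotein, was at least 185-fold lower, at 33.5 against 17910.

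Lipogenesis and triglyceride synthesis genes had a median log2 ratio of 0.77, above all random lists, with 9 of 22 at least 2-fold higher and 0 lower. Besides Pnpla3, fatty acid synthase (Fasn) was 4.81-fold, acetyl-CoA carboxylase (Acaca) 4.43-fold and the elongase Elovl6 3.94-fold higher on their brightest probe sets, but another probe set of Acaca had a log2 ratio of -0.11. The desaturase Scd was 2.13-fold and Srebf1 1.88-fold higher, with another probe set of Srebf1 at -0.09. Glycolysis, fructose and pentose phosphate genes had a median of 0.28 at the 99.84th percentile and 3 of 19 genes at least 2-fold higher, 0 lower: Pgd, an enzyme of the pentose phosphate pathway, 2.41-fold, Taldo1 2.23-fold and liver pyruvate kinase (Pklr) 2.11-fold higher. Lipid droplet and PPARG targets did not stand apart, with a median of 0.12 at the 80.8th percentile, 2 of 18 at least 2-fold higher and 1 lower. Fabp4 was at least 8.09-fold and Cidea 2.67-fold higher, and Cd36 2.71-fold lower. Fatty acid oxidation and PPARA targets had a median of -0.22 at the 0.01th percentile, with 1 of 28 at least 2-fold lower and 2 higher. The carnitine acetyltransferase Crat was 2.31-fold lower, but Fgf21 3.05-fold and Vnn1 2.56-fold higher.

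The gluconeogenesis and fasting list had a median of -0.25 at the 0.06th percentile, with 5 of 19 at least 2-fold lower and 0 higher. Serine dehydratase (Sds) was 7.43-fold, tyrosine aminotransferase (Tat) 6.94-fold and Igfbp1 3.03-fold lower, while the enzymes of gluconeogenesis itself went both ways: Pck1 was 1.22-fold lower, pyruvate carboxylase (Pc) 1.26-fold and fructose bisphosphatase (Fbp1) 1.03-fold higher. Amino acid and urea metabolism genes had a median of -0.21 at the 0.02th percentile, with 4 of 32 at least 2-fold lower and 1 higher. Besides Sds, ornithine aminotransferase (Oat) was 4.66-fold, histidase (Hal) 2.24-fold and argininosuccinate lyase (Asl) 2.19-fold lower. Within the endoplasmic reticulum and amino acid stress list, whose median of 0.16 did not stand apart, 7 of 25 genes were at least 2-fold higher. They included the serine synthesis enzyme Psat1 at 14.3-fold, Asns at 7.32-fold and Trib3 at 3.01-fold. The stress factor Atf3 had a log2 ratio of 1.9986. Bile acid synthesis and transport genes had a median of -0.37 and xenobiotic genes of -0.39, both below all random lists, with 2 of 18 lower and 0 higher, and 2 of 21 lower and 1 higher, at 2-fold. The sterol hydroxylase Cyp8b1 was 2.39-fold, Cyp3a9 4.14-fold and Cyp1a2 2.82-fold lower. Heat shock genes had a median of -0.34 at the 0.08th percentile, with 2 of 11 at least 2-fold lower and 0 higher and the cochaperone Stip1 3.02-fold lower.

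Stellate cell and matrix markers had a median of 0.99, above all random lists, with 7 of 15 at least 2-fold higher and 0 lower. The metalloproteinase inhibitor Timp1 was at least 5.83-fold, Tagln at least 4.09-fold, collagen Col3a1 3.88-fold and decorin (Dcn) 3.32-fold higher. Medians of other cell type lists were 0.43 for endothelial markers, 0.29 for Kupffer cell and macrophage markers, 0.74 for 5 bile duct markers, 0.59 for 6 lymphocyte markers, 0.45 for 5 red blood cell markers and 0.49 for 6 adipocyte markers, all above the middle 95% of random lists. The lymphocyte median turned to -0.0907 with the lower floor, and the red blood cell list did not stand apart in at least 1 other setting. At 2-fold, 1 of 14 endothelial, 3 of 18 macrophage, 1 bile duct, 1 lymphocyte, 1 red blood cell and 2 adipocyte markers were higher and 0 lower. Hepatocyte markers lay at -0.13, at the 5.69th percentile, with 1 of 16 lower, Tat. Interferon response genes had a median of 0.27 at the 98.99th percentile, with 4 of 22 at least 2-fold higher and 0 lower, led by viperin (Rsad2) at 2.80-fold. Lipoproteins lay at -0.15 at the 2.19th percentile with 0 of 18 at 2-fold. The interferon, lipoprotein and cell cycle lists did not stand apart in at least 1 other setting. STAT targets and immediate early genes had a median of 0.36, above all random lists, with 6 of 24 at least 2-fold higher and 2 lower, Myc 3.35-fold and the growth arrest gene Gadd45a 3.16-fold higher. Cell cycle genes had a median of 0.46 at the 99.92th percentile, with 2 of 18 at least 2-fold higher and 0 lower, among them the mitotic kinase Cdk1 at least 2.83-fold. The clock list had a median of 0.36 at the 99.66th percentile, with 1 of 16 genes 2-fold higher, Dbp, and Bmal1, the rat symbol of Arntl, 1.77-fold lower.

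Female-biased liver genes had a median of -0.92 in rats, below all random lists, with 5 of 10 at least 2-fold lower and 0 higher. Besides A1bg, the transcription factor Cux2 was 4.86-fold, the prolactin receptor Prlr 4.24-fold and Sult2a2 2.88-fold lower. The male-biased list had a median of -0.14 at the 5.01th percentile, with 2 of 13 at least 2-fold lower and 0 higher and the aldo-keto reductase Akr1b7 9.59-fold lower. Probe sets annotated to Xist and to Y-linked genes both had signals on the rat arrays, although the labels say male; these genes were chosen after their values were seen. Whether the Xist probe sets of this platform bind another transcript was not tested. Xist, the RNA of the inactive X chromosome, had 4 probe sets with signals of at least 977.9 on every rat array. The Y-linked genes Eif2s3y and Uty had signals of at least 782.9 on their brightest probe sets, and another probe set of Uty was under the floor. From WT to saline mutant the Xist log2 ratios ran from -0.99 to -0.51, that of Eif2s3y was 0.68 and that of Uty -0.45. Male-specific Cyp2c11 and female-specific Cyp2c12, which belong to a family of similar sequences, had WT signals of 29009 and 36492. On the mouse arrays the highest Xist signal was 54.3, under the floor, and Eif2s3y had signals of 2709 to 3136.

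Genes of leptin, insulin and growth hormone signalling had a median of -0.21 at the 0.14th percentile, with 6 of 22 at least 2-fold lower and 1 higher. Igfbp2 was 6.57-fold lower in the mutant rat, Lepr 1.26-fold higher with probe sets in both directions, and Socs3 at least 1.27-fold lower at signals near the floor. Other large ratios were higher for the annexins Anxa8 (at least 10.2-fold) and Anxa5 (8.63-fold), Tsx (at least 7.87-fold), the potassium channel Kcnj15 (6.70-fold) and lymphotoxin beta, Ltb (at least 6.20-fold). Lower were the pancreatic carboxypeptidase Cpa1 (9.85-fold), Slc25a45 (5.90-fold), Trim24 (5.56-fold), Mmd2 (at least 5.28-fold) and the protease inhibitor Mug1 (5.19-fold). In all, 22 of 32 lists stood apart, and the probe set spread was 0.43. Of the genes named for their large ratios, Fabp4, Tsx, Asns, Ltb, Timp1, Slc25a45 and Mmd2 were under 2-fold in at least 1 other setting. Floors at the 25th and 75th percentile gave 694 and 112 genes higher and 453 and 74 lower.

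**Figure D2:**
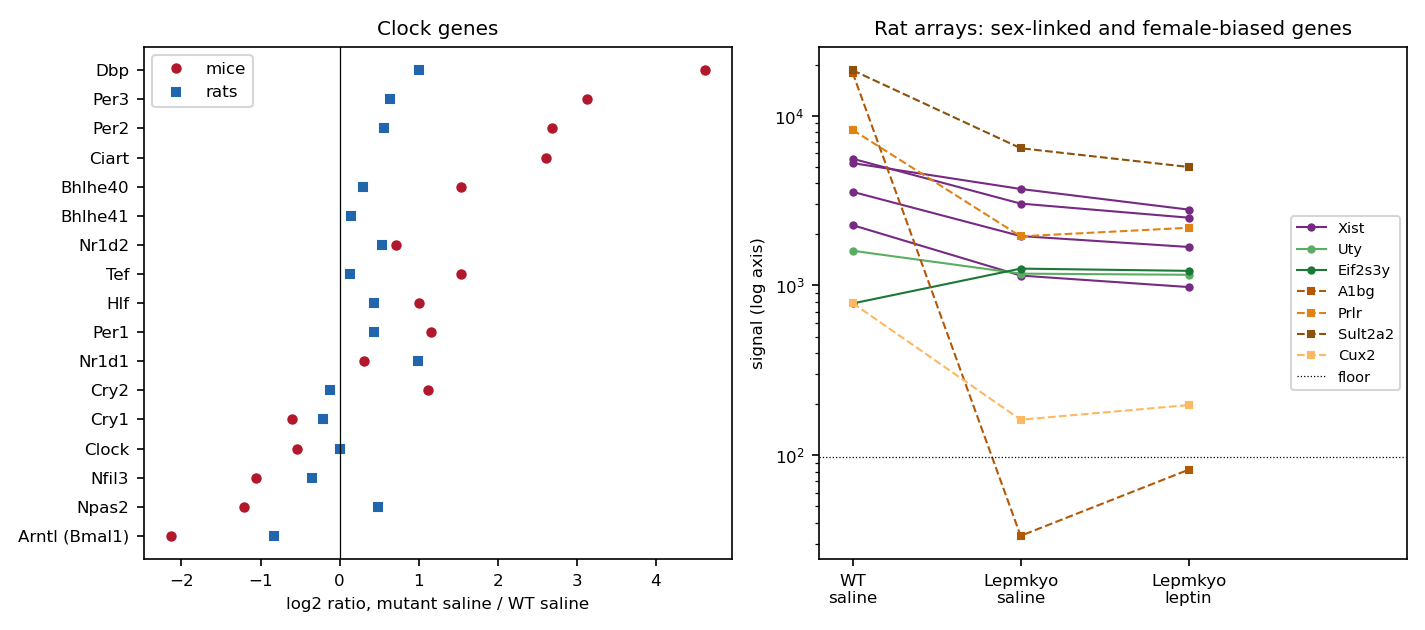
Left, log2 ratio of each measured clock gene in saline mutant over WT saline liver, in mice (circles) and rats (squares), 1 array per group. Right, signal on a log axis of Xist, Y-linked Uty and Eif2s3y (solid lines, 1 per probe set above the floor in WT) and of A1bg, Prlr, Sult2a2 and Cux2 (dashed lines) on the 3 rat arrays, with the floor of 97.0 dotted; A1bg went from 17910 to 33.5, and the Xist probe sets stayed at 977.9 or more.

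In leptin-injected mutant rats, as in mice, few genes were far from the saline array. Of 9705 genes, 23 were at least 2-fold higher and 27 at least 2-fold lower. The cell cycle list and the list of STAT targets and immediate early genes had lower medians. Both had higher medians in the rat genotype comparison, which shares the saline mutant array. The acute phase list had a slightly higher median, with alpha-2-macroglobulin its only member at 2-fold. Simulated unchanged arrays gave 3.34, 39.3 or 143 genes 2-fold apart under the 3 noise models, beside the 50 measured, so no excess over noise is claimed.

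A2m, the rat acute phase protein alpha-2-macroglobulin, was 6.79-fold higher, at 1981 against 291.8. The acute phase list had a median log2 ratio of 0.18 at the 99.96th percentile, with 20 of 21 above 0, 1 of them at 2-fold and 0 lower, among them the endotoxin-binding protein Lbp at 1.39-fold and Lrg1 at 1.35-fold higher. Il1rn was 1.40-fold lower. After quantile normalization the acute phase list did not stand apart. STAT targets and immediate early genes had a median of -0.15 at the 0.05th percentile, with 4 of 22 at least 2-fold lower and 0 higher. Cish, a feedback inhibitor of cytokine receptors, was 4.16-fold lower on its brightest probe set and had a log2 ratio of -0.22 on another. The zinc finger factor Egr1 was 2.75-fold, Myc 2.11-fold, Atf3 2.01-fold and Fos 1.08-fold lower. Of this list, 17 genes lay below 0 and 5 above. Stat3 was 1.35-fold higher, with another probe set at a log2 ratio of 0.68. Bcl3 was 1.34-fold higher, with another probe set at -0.17, and Junb 1.20-fold higher. Cell cycle genes had a median of -0.43, below all random lists, with 2 of 18 at least 2-fold lower and 0 higher: Cdk1 2.33-fold and Cdkn3 2.21-fold lower. The securin Pttg1 was 2.55-fold and Cdca3 at least 2.75-fold lower. Many of these genes had signals close to the floor of 97.0; that of Cdk1 was 117.5 after leptin.

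The gluconeogenesis and fasting list had a median of -0.16 at the 0.02th percentile, with 1 of 19 genes at least 2-fold lower, the coactivator Ppargc1a, 0 higher, and Foxo1 1.91-fold lower. Fatty acid oxidation and PPARA targets had a median of -0.09 at the 0.12th percentile, with 21 of 28 below 0. Endoplasmic reticulum and amino acid stress genes had a median of 0.15 at the 99.84th percentile, with 1 of 25 at least 2-fold higher, the serine synthesis enzyme Phgdh, and 1 lower, Atf3. Heat shock genes had a median of 0.19 at the 99.63th percentile, with Stip1 1.55-fold higher, and endothelial markers one of 0.20 at the 99.73th percentile, both with 0 genes at 2-fold. Exocrine pancreas markers lay at -0.39 over 3 genes. The endothelial and pancreas lists did not stand apart in at least 1 other setting. The lipogenesis, clock and female-biased lists did not stand apart. In the first Gpam was 1.81-fold lower, and in the bile acid list Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.14-fold higher. The clock list holds genes of opposite phase, which can offset each other. Its Per and Dbp phase had a median of 0.00 over 9 genes and the opposite Bmal1 phase -0.46 over 5. These medians were not placed among random lists.

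Among the largest ratios, the death receptor Tnfrsf21 was 4.59-fold, the protocadherin Pcdh18 2.56-fold, the desaturase Scd2 2.46-fold, Myorg 2.30-fold, heme oxygenase 1 (Hmox1) 2.22-fold, Shq1 at least 2.19-fold, Lmo7 2.17-fold, the neurotrophin Ntf3 2.16-fold and Lin7a 2.16-fold higher. Slc45a3 was 3.07-fold, the tight junction protein Cldn1 2.87-fold, Cib2 2.66-fold, the clock factor Npas2 2.51-fold and Asb5 2.26-fold lower. Of the 20 genes with the largest ratios, Tnfrsf21, Pcdh18, Myorg, Lmo7, Lin7a, Cish, Slc45a3, Cldn1, Npas2 and Asb5 were under 2-fold in at least 1 other setting, and another probe set of Lmo7 had a log2 ratio of -0.09. Igfbp2 was 1.67-fold lower, Lepr 1.05-fold lower, and Scd, Srebf1 and Pck1 were 1.02-fold to 1.10-fold higher. Socs3 was under the floor on both arrays. All 4 Xist probe sets were lower in the leptin array than in the saline mutant array, 1 of them at 2796 against 3699. Y-linked Eif2s3y was at 1218 against 1256. If the probe sets measure Xist, a different share of female RNA on these arrays cannot be told apart from an effect of leptin. The probe set spread was 0.24, and 9 of 32 lists stood apart. The rat saline mutant array is likewise in the genotype and leptin ratios, so its own deviations can also move these medians. Of the lists that stood apart, cell cycle, STAT, heat shock, pancreas and acute phase had genotype medians of the opposite sign (0.46, 0.36, -0.34, 0.39 and -0.03). The fatty acid oxidation, fasting, endoplasmic reticulum stress and endothelial lists had genotype medians of the same sign. With the floor at the 75th percentile 8 genes were higher and 5 lower, and with it at the 25th percentile 211 and 296.

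Mice and rats shared part of the genotype difference. Of 8303 genes matched by symbol, 61 were at least 2-fold higher and 15 at least 2-fold lower in both mutants. Independent lists would share 10.4 and 3.34, and the highest total of 10000 random rematchings was 29, against 76. Another 12 genes were 2-fold apart in opposite directions. Across genes, which are not independent replicates, the log2 ratios correlated at r = 0.22 (Spearman 0.22). Genes higher in both, named here after their values were seen as those with the largest smaller ratio, were Esm1 (at least 5.23-fold in mice and at least 5.21-fold in rats), the annexins Anxa2 (7.92-fold and 4.58-fold) and Anxa5 (4.48-fold and 8.63-fold), the macrophage elastase Mmp12 (at least 7.55-fold and at least 4.07-fold) and galectin 3, Lgals3 (8.82-fold and 4.06-fold). Lower in both were Igfbp2 (12.7-fold and 6.57-fold), the leukemia inhibitory factor receptor Lifr (3.66-fold and at least 4.17-fold), the mitochondrial carrier Slc25a30 (5.44-fold and 3.55-fold) and the liver transcription factor Onecut1 (8.03-fold and 3.04-fold). Renamed genes that carry different symbols in the 2 species, such as Arntl and Bmal1, were missed by this matching.

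After leptin, 0 genes were at least 2-fold apart the same way in both species. At 1.5-fold, a size added after the data were seen, 8 genes were higher and 15 lower in both, and 1 went opposite ways, over 8213 genes. The total of 23 compares with at most 21 in random rematchings, but by direction the rematchings reached 12 higher and 15 lower, no fewer than measured. The correlation across genes was r = 0.09 (Spearman 0.09). Lower in both, and chosen after their values were seen, were the transcription factors Egr1 (log2 -0.73 in mice and -1.46 in rats), Myc (-0.75 and -1.08) and Nr1d1 (-1.13 and -0.60). Pcdh18 was higher in both (at least 0.71 and 1.36). With the lower floor, 25 genes were 2-fold apart the same way.

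**Figure D3:**
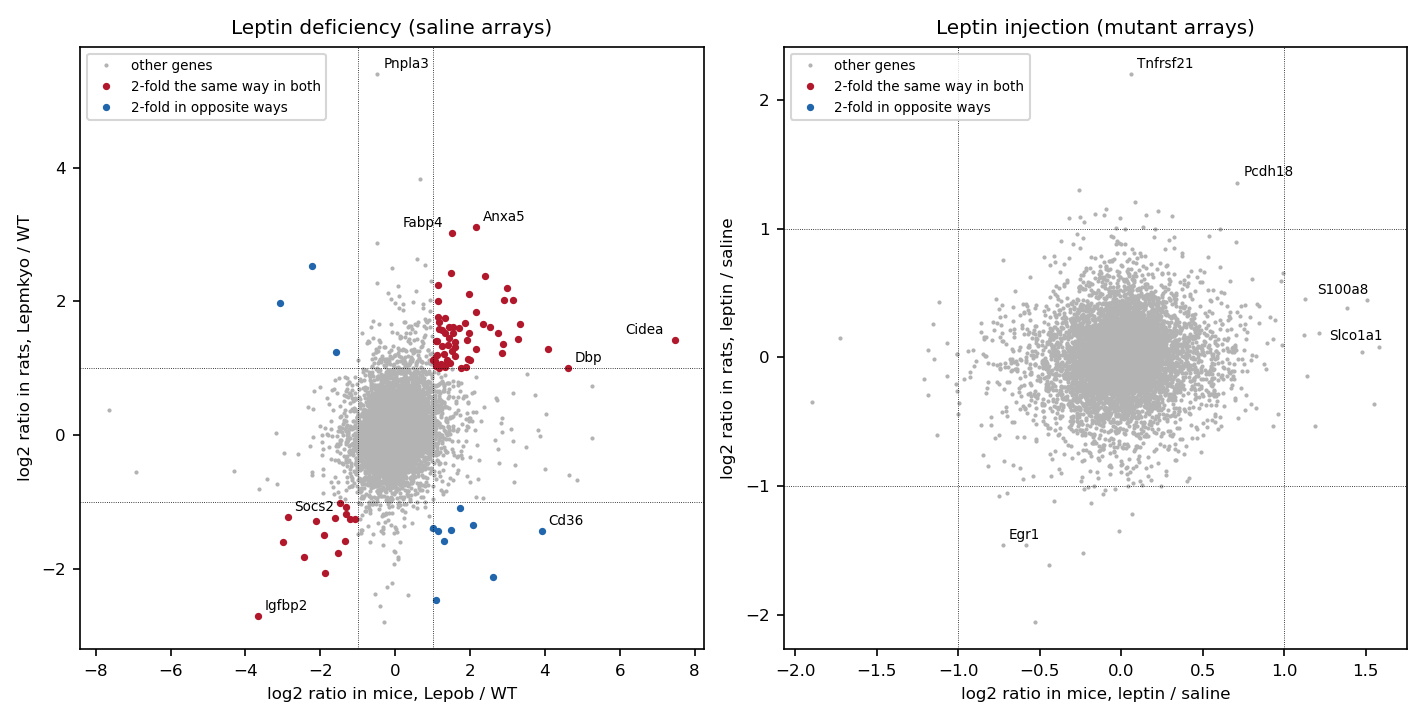
Log2 ratio of each gene in mice (horizontal axis) and rats (vertical axis), left for saline mutant over WT saline and right for leptin over saline in mutants, 1 array per group; dotted lines mark 2-fold. At left 76 genes lie past 2-fold the same way and 12 in opposite ways, and at right 0 do.

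Some genes that differed by genotype moved in the direction of WT from the saline mutant to the leptin array. Of 976 such genes in mice, 96 (9.84%) moved at least 1.5-fold toward WT, and 15 moved away. The exact 95% interval of that share was 8.04% to 11.9% and covers counting only. Of 436 such genes in rats, 66 (15.1%, interval 11.9% to 18.9%) moved toward WT and 6 away. Any gene that passed its WT level was counted as moved toward it. The saline mutant array is in both ratios, so its own chance deviations give such a movement with no effect of leptin. In simulated unchanged arrays, 48.9% to 50.8% of genes 2-fold apart by genotype moved toward WT in mice, depending on the noise model. In rats it was 39.1% to 49.9%. All such simulated genes are noise, so these shares set no chance level for the measured ones. The genotype comparison of the other species holds none of these arrays, and genes chosen by it took their direction from that species. In mice 16 of 346 such genes moved at least 1.5-fold against the rat genotype difference and 5 along it. In rats 25 of 624 moved against the mouse genotype difference and 26 along it. The WT array of the species itself does not enter the direction of these counts. In mice Slco1a1, Cyp7b1 and Cyp2b13 lay nearer WT. In rats Igfbp2 lay 1.67-fold farther from WT. At a floor at the 25th percentile the shares were 28.9% in mice and 31.5% in rats, and at the 75th 4.09% and 9.14%.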

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

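The tests of the 3 patterns weighed here were all chosen after the values they bear on were seen; of the noise models, the first was set before its output was seen and the other models after it. The differences between mice and rats given first were not tested, since each group is 1 array.

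Some lists stood apart in opposite directions in the genotype comparisons of mice and rats. The median log2 ratio in mice minus that in rats was 1.12 for fatty acid oxidation and PPARA targets, 0.85 for gluconeogenesis and fasting genes and 0.79 for xenobiotic metabolism. It was -1.64 for 5 bile duct markers and -1.01 for red blood cell markers, of which 4 were measured in mice and 5 in rats. The mouse value of the red blood cell list turned sign in other settings, and the mouse gluconeogenesis and bile duct lists and the rat red blood cell list did not stand apart in at least 1 other setting. Of the 12 genes 2-fold apart in opposite directions, those with 1 of the largest ratios of a comparison or among the 4 largest of a list were singled out. The difference of log2 ratios, mouse minus rat, was 5.37 for the fatty acid translocase Cd36, 3.56 for the transcription cofactor Trim24, at least 2.81 for the hydroxyacid oxidase Hao2, at least 2.58 for the stress gene Gadd45b and -2.81 for the immediate early factor Egr1. Another mouse probe set of Gadd45b had a log2 ratio of -1.01, the same direction as in rats. Hao2 is in the female-biased lists of both species, with a rat log2 ratio of -1.09. If the rat Xist probe sets measure Xist, this rat ratio cannot be told apart from a larger share of female RNA on the WT array. Outside this choice, and named after their values were seen, the log2 ratios in mice and rats were -3.08 and 1.98 for Dmbt1, 2.62 and -2.13 for Abhd2 and -2.22 and 2.52 for the fatty acid binding protein Fabp5.

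Sex-linked and female-biased genes stood out on the rat arrays. The lowest signal of any Xist probe set on any rat array was 977.9, and that of the brightest probe sets of Y-linked Eif2s3y and Uty 782.9 (another Uty probe set was at most 36.0), against a floor of 97.0, which is consistent with RNA of both sexes on each rat array, as pooling of animals could give; that the Xist probe sets bind another transcript was not tested and stays open. If they do measure Xist, a larger share of female RNA on the WT array could lower female-biased genes only as far as Xist, and 4 of 10 members (A1bg, Cux2, Prlr and Sult2a2) lay beyond the lowest Xist ratio by more than the probe set spread of 0.43, so under that condition such a share is not the whole cause. For the other 6 members, with a median of -0.60, it cannot be told apart from an effect of genotype, because each group is 1 array. Among them Acot1 was higher in the mutant (log2 ratio at least 0.58, with a WT signal under the floor) and the rest were lower. The Y-linked genes went both ways, Eif2s3y at 0.68 and Uty at -0.45. An effect of leptin deficiency stays open and untested.

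Clock genes differed between the WT and mutant mouse arrays. The tables argue against scaling of the arrays, since the list's median was 1.15 after quantile normalization. The median of the Per and Dbp arm exceeded that of the Arntl arm by 2.59. Such opposite arms would follow from collection at different clock hours, which cannot be told apart from an effect of genotype on the clock or on feeding time, since collection hours were not stated and each genotype is 1 saline array.

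More genotype-changed genes moved toward WT than away from it after leptin, but the saline mutant array is in both ratios. Among genes chosen in the other species, 16 in mice moved against that species' genotype difference and 5 along it. In rats the counts were 25 and 26. With the leptin ratio from another probe set, 18 of the 275 genotype-changed genes with a second probe set in mice moved toward WT and 5 away. That is a share of 78.3% (exact 95% interval 56.3% to 92.5%, taking genes as independent), against 17 and 1 on the same probe set. These counts argue against noise of single probe sets as the whole cause in mice. In rats 5 of 59 moved toward WT and 4 away (55.6%, 21.2% to 86.3%), against 9 and 0 on the same probe set. With so few genes, noise of single probe sets cannot be told apart from a movement toward WT. Over all genes the covariance of the ratios from different probe sets was -0.0187 in mice and -0.0084 in rats, 38.9% and 26.1% of that within a probe set, while against simulated arrays the observed covariances of -0.0537 and -0.0357 lay above those of the first noise model (-0.0638 and -0.0496) and below those of the second (-0.0447 and -0.0317) and the third (-0.0317 and -0.0265). A deviation of the saline mutant sample itself, shared by all probe sets of a gene, was not tested and stays open beside an effect of leptin, as that group is 1 array.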

How the results depend on the processing

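The size of 1.5-fold and the second and the third noise model were chosen after seeing the data. No paired analysis was possible because each group is 1 array and the labels carry no replicate numbers; for the same reason no replicate could be left out. Quantile normalization, centring, the median over probe sets and leaving out _x_at and _s_at probe sets moved none of the 16 main counts and shares by more than 1.5 times or beyond their interval. The floor moved most of them: 12 at the 25th percentile and 11 at the 75th. Dimmer signals enter with the lower floor, and dim genes drop out or have smaller bounds with the higher one, by construction. How much of the added counts is noise was not tested. All counts therefore depend on how dim signals are treated, those after leptin most.

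With the floor at the 25th and 75th percentiles, mouse genotype gave 984 and 267 genes higher and 1341 and 198 lower; mouse leptin 408 and 5 higher and 436 and 4 lower; rat genotype 694 and 112 higher and 453 and 74 lower; rat leptin 211 and 8 higher and 296 and 5 lower. Shares moved toward WT were 28.9% and 4.09% in mice and 31.5% and 9.14% in rats. Genes alike in both species numbered 158 and 37 for genotype, and 25 for leptin at the 25th percentile. At 1.5-fold, leptin counts were 252 higher and 255 lower in mice, 204 and 251 in rats, and 23 alike in both.

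Of 65 lists that stood apart, 47 did so the same way in every alternative that gave them a value. With the floor at the 25th percentile the lymphocyte medians changed sign, to -0.0458 (mouse genotype), 0.20 (mouse leptin) and -0.0907 (rat genotype). The mouse genotype median of red blood cell markers became 0.0411 after quantile normalization, 0.0172 after centring, 0.13 with the lower floor and 0.0135 with the median over probe sets. Clcn5 after leptin in mice became -0.0466 with the median over probe sets and -0.0466 without _x_at and _s_at. The causes were not tested. All 20 genes with the largest ratios stayed past 2-fold in every alternative with a value in the mouse genotype comparison, 13 of 20 in rats, and after leptin 15 of 20 in mice and 10 of 20 in rats; only 6 of the 20 in mice after leptin had a value in every alternative. A2m was among those that stayed, and Cish, Tnfrsf21, Lce1h and Slco1a1 were not. Genes 2-fold apart in simulated unchanged arrays fell from 301 to 139 and 27.6 in mice with the second and the third noise model. In rats they fell from 143 to 39.3 and 3.34. Whether leptin counts exceed the noise between probe sets therefore depends on the model. None of the models holds variation between animals, so none can show an excess over that.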

Other observations

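Lists not described so far lay within the range of random lists, and their median log2 ratios were as follows. In the mouse genotype comparison lipoproteins lay at -0.05, with 3 of 18 at least 2-fold higher and 1 lower; Apoa4, an apolipoprotein, was 8.53-fold higher. Bile acid genes lay at -0.03 (2 of 21 higher, 4 lower), with the rate-limiting enzyme Cyp7a1 2.33-fold higher on its brightest probe set and Cyp7b1 far lower. STAT targets and immediate early genes lay at 0.13 (6 of 27 higher, 3 lower), with Gadd45a 5.12-fold higher and Egr1 2.98-fold lower, and interferon response genes at 0.01 (2 of 23 higher, 2 lower), with Gbp2 2.48-fold higher and Stat2 2.57-fold lower. Heat shock genes lay at -0.21 (0 of 12 higher, 2 lower), oxidative phosphorylation at 0.13 (0 of 30 at 2-fold), cell cycle at 0.10 (1 of 19 higher, the inhibitor Cdkn1a at 4.86-fold), and endothelial markers at 0.25 (2 of 17 higher), with Lyve1 3.88-fold higher. Neutrophil markers lay at 0.23 (2 of 7 higher), with S100a8 3.19-fold and S100a9 2.45-fold higher in the saline mutant, so both were higher again after leptin. Exocrine pancreas and skeletal muscle markers lay at -0.05 and -0.02.

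After leptin in mice, medians were 0.00 for fatty acid oxidation, -0.06 for lipid droplet, 0.03 for gluconeogenesis, 0.02 for bile acid genes, 0.05 for lipoproteins, -0.10 for the clock, 0.05 for leptin, insulin and growth hormone signalling and -0.02 for NRF2. They were 0.06 for heat shock, 0.02 for amino acid metabolism, -0.03 for cell cycle, 0.02 for hepatocyte, 0.01 for stellate cell, -0.08 for endothelial, 0.08 for bile duct, -0.13 for red blood cell, -0.11 for adipocyte, -0.17 for pancreas and -0.06 for muscle markers. Besides Slco1a1 of the bile acid list and Nr1d1 of the clock list, 0 members of these lists were 2-fold apart.

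In the rat genotype comparison cholesterol synthesis lay at 0.09 (0 of 20 at 2-fold), acute phase proteins at -0.03 (2 of 21 higher, with A2m 2.55-fold higher), NRF2 genes at -0.07 (1 of 18 lower, Mt2A at 3.21-fold), oxidative phosphorylation at 0.09 (0 of 29 at 2-fold), neutrophil markers at 0.37 and pancreas markers at 0.39 over 3 genes each. Cpa1, a pancreatic enzyme, had a WT signal of 2948. Muscle markers had 2 measured genes and so no median in rats.

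After leptin in rats, medians were 0.02 for lipogenesis, 0.07 for cholesterol synthesis, -0.09 for lipid droplet, 0.04 for glycolysis, -0.04 for bile acid genes, 0.09 for lipoproteins, -0.07 for interferon response, -0.02 for the clock and -0.03 for leptin, insulin and growth hormone signalling. They were 0.12 for male-biased, -0.05 for female-biased, 0.03 for xenobiotic, 0.05 for NRF2, 0.08 for amino acid and 0.04 for oxidative phosphorylation genes. Marker medians were 0.11 for hepatocyte, 0.09 for macrophage, 0.04 for stellate cell, 0.20 for bile duct, -0.13 for lymphocyte, 0.38 for neutrophil, 0.07 for red blood cell and -0.23 for adipocyte. The sterol regulator Insig1, Npas2, Cish and Ucp2 (2.19-fold) were lower and Cyp7a1 and Hmox1 higher at 2-fold among these lists.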
